A study of Homo sapiens with 6 samples.

How the data were processed

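The series measured poly(A)-selected RNA from HaCaT cells, an immortalized human keratinocyte line. Cells carrying a CRISPR guide against STUB1 were compared with cells carrying a control guide, 3 libraries in each group. STUB1, also called CHIP, is an E3 ubiquitin ligase that binds the HSP70 and HSP90 chaperones. Per the labels, guides were delivered with a lentiviral vector, cells were sorted into plates, and colonies were screened for the STUB1 protein by immunoblot. Libraries were made with an Illumina TruSeq RNA kit after oligo(dT) selection. The labels do not say whether the 3 libraries of a group came from separate clones, separate cultures or 1 preparation, so p-values measure only the spread between these libraries, which may be technical.

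The deposited table gave 1 FPKM value (fragments scaled to transcript length and to the mapped total of the library) for each of 20014 Ensembl genes in each of 6 libraries, rounded by the authors to 3 decimals. The submitters' processing notes name Trimmomatic 0.36, HISAT2 2.0.5, featureCounts 1.6.3, edgeR 3.6.3, Cufflinks with no version, and the genome build GRCh38.p13, without saying which tool did what. Annotation release, read filters, strand setting and any scaling between libraries are not given in the sources used here. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart, and genes with near-identical copies may share reads.

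FPKM divides by transcript length and library total, so it is no count, and no count test was run. The FPKM sums ranged from 410756 to 447332 and were therefore not TPM. Depth was estimated from low values: among genes of 300 to 2000 exonic bases, the FPKM times the exonic length moved in steps that imply library sizes of 45700000 to 52900000 reads. Only 57.1% to 62.3% of 429 to 467 low values per library lay within 0.15 of a whole number of reads, so these sizes are estimates and reads were not recovered. No confidence interval from counting error was therefore computed.

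Gene symbols came from a table of Ensembl identifiers for 19991 genes and from GENCODE 29 for the other 23. Coordinates, exonic length and GC content came from GENCODE 29 on GRCh38, which held 19873 of the identifiers. Of the tested genes, 11177 had GC content and length. No column belonged to a sample outside the 6 labelled here.

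Genes with a mean FPKM of at least 1 over the 6 libraries were tested (11262 genes; 3232 genes were at 0 in every library). Values were log2(FPKM + 1), with a pseudocount of 1, and fold changes are on that scale, which understates changes of low genes. The test was limma 3.58.1 in R 4.3.3, with genotype as the sole term, an intensity trend in the variance prior and Benjamini-Hochberg adjustment at 0.05. A change of at least 2-fold meant an absolute log2 value of at least 1. Groups of 3 against 3 allow 10 splits, so an exact two-sided permutation test cannot go under 0.1. Tables and plots used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

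Before the data were examined, 27 gene lists were fixed from textbook knowledge. Those with at least 3 tested members (24 lists) were tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The lists covered EDA/EDAR receptor signalling, NF-kB subunits and regulators, NF-kB targets, EDAR targets in skin appendages, basal, differentiating, wound-associated and simple-epithelial keratinocyte genes, junctions, epithelial-mesenchymal transition, TGF-beta response, cytosolic heat shock, unfolded protein and integrated stress response, p53 targets, proliferation, interferon-stimulated genes, Wnt targets, EGFR ligands and feedback, hypoxia, NRF2 targets, cholesterol synthesis, STUB1 neighbours, histones, mitochondrially encoded mRNAs, and fibroblast, melanocyte and leukocyte markers.

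Genes are named in the text by a rule fixed at the same time. It takes STUB1, its neighbour JMJD8, EDA, EDAR and EDARADD whatever their values. It takes the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 FPKM in the higher group and no overlap between groups, pseudogenes and unnamed loci left out. From lists that passed, and from lists on EDAR, NF-kB, keratinocyte state, junctions and chaperones, it takes up to 4 members with the smallest p. Other genes named below, among them further list members and genes of chromosomes 6 and 17, were chosen after their values were seen. Some genes that the rule takes are not reported here.

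Replicate numbers are shared between the groups. The deviations from the group means correlated across genes, between same-numbered libraries, at 0.375, 0.150 and 0.188. All were above 0.1, so by the rule set in advance the numbers were taken to pair the libraries. No label states a shared day or batch, and deviations within a group cancel out, so these correlations are weak evidence of pairing. The fit with the replicate number as a block was an alternative. Other alternatives fixed in advance were a pseudocount of 0.1, no filter, a filter of mean FPKM of at least 5, median-of-ratios scaling, division by the library sum (TPM), no variance trend, array weights, an estimated correlation for the lists, and leaving out each library. Added after the data were seen were a per-library correction for GC content and transcript length, the same with the replicate block, and leaving out the genes of 2 chromosome regions.

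The search along chromosomes was also chosen after the data were seen. It took medians of log2 fold changes in windows of 20 Mb holding at least 15 tested genes. It then sought 1 change point per chromosome, at least 30 genes from either end, against 1000 shuffles of the gene order. Change points were placed on fold changes after the GC and length correction.

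Limma, camera and the change point search were first tested on simulated data. For the comparison of knockout with control over 11262 genes, limma recovered 65.7% of planted changes of 0.5 on the log2 scale, 98.5% of changes of 1 and 100% of changes of 2, and 3.3% of its calls were false. In 20 draws without effects it made 0 calls at the adjusted threshold. The simulated noise was independent between genes and libraries, without the GC and length trends that these libraries share across genes. These rates therefore do not measure the error in the real data.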

Results

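Gene expression was measured in 6 libraries from HaCaT keratinocytes, 3 from cells carrying a STUB1 knockout and 3 from control cells. The series title names EDAR, the ectodysplasin receptor, and NF-kB, so the comparison addressed which keratinocyte genes, and which members of that pathway, differed once STUB1 was disrupted. Between 11200 and 11292 genes reached 1 FPKM in each library, and estimated library sizes ran from 45700000 to 52900000 reads. Mitochondrially encoded transcripts made up 20.9% to 30.8% of all FPKM. Libraries of a group correlated across genes at Pearson's r of 0.996 to 0.999 in the knockout and 0.986 to 0.998 in the control. Control 3 stood apart, with r of 0.988 and 0.986 to controls 1 and 2. Its level relative to the mean of the 6 libraries changed with transcript length by -0.144 log2 units per doubling. The other 5 libraries had 0.0153 to 0.0423, but such slopes cancel out over the libraries, so these values partly mirror control 3. Without control 3 the rank correlation of fold change with length went from 0.0978 to -0.112.

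STUB1 mRNA was lower in every knockout library than in any control library. It measured 23.2 ± 1.55 FPKM (SD, n = 3) in the knockout and 44.1 ± 7.67 FPKM (SD, n = 3) in the control, 52.5% of the control mean. The log2 fold change was -0.89 (SE 0.116; limma, Benjamini-Hochberg adjusted p = 0.00125). The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. STUB1 lies on chromosome 16 at 680224 to 682870 (GRCh38), and its 3' end shares 983 exonic bases with JMJD8 on the opposite strand. JMJD8 fell as well, from 35.8 ± 4.60 to 25.9 ± 1.77 FPKM (log2 fold change -0.44, limma with Benjamini-Hochberg adjusted p = 0.0142). Without a stated strand setting, reads of the shared stretch cannot be assigned to either gene. The JMJD8 call was lost without knockout 1 (adjusted p = 0.063) or without knockout 3 (adjusted p = 0.0576). A frameshifting edit need not remove the mRNA, so the residual STUB1 signal does not measure protein.

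**Figure D1:**
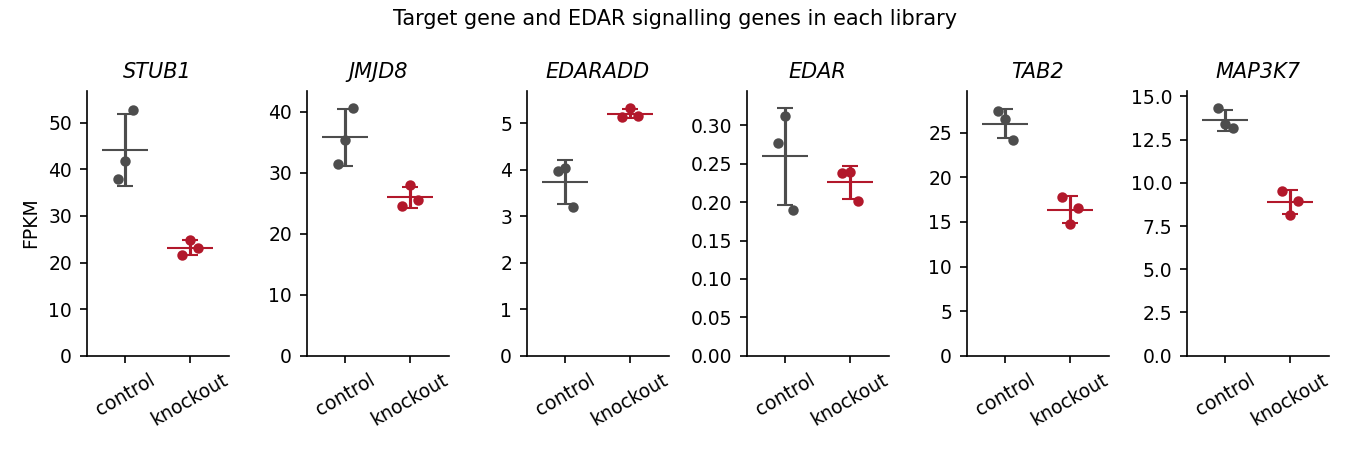
FPKM of STUB1, its overlapping neighbour JMJD8 and 4 genes of EDAR signalling in each library (points), with the mean and SD (n = 3 per group). STUB1 averaged 23.2 FPKM in the knockout and 44.1 FPKM in the control, while EDAR stayed under 1 FPKM in both groups.

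On the log2(FPKM + 1) scale, S100A7, S100A9 and S100A8 rose most among genes under the naming rule and KRT13 fell most, while by the ratio of FPKM means UBD fell further (13.5-fold). S100A7 (psoriasin), a keratinocyte antimicrobial protein, went from 4.46 ± 0.407 to 73.5 ± 3.24 FPKM, 16.5-fold (log2 fold change 3.77). Its neighbours S100A9 and S100A8, which form calprotectin, rose 9.5-fold and 8.66-fold. KRT13, a keratin of mucosal epithelia, went from 244.2 ± 38.5 to 21.2 ± 1.12 FPKM, 11.5-fold lower (log2 fold change -3.46). Among 11262 tested genes, 2579 (22.9%) changed, 1079 higher and 1500 lower, and 41 of them changed at least 2-fold, 21 higher and 20 lower (limma, Benjamini-Hochberg). Expressed as TPM, which rescales each library by its sum, the split was 667 higher and 1622 lower, so higher genes made up 29.1% of calls against 41.8%. The groups did not overlap for 5138 genes (45.6%), where chance gives 10% for any single gene. Genes share library-wide trends, such as that with GC content, so the gap between these shares does not measure an effect of genotype. Leaving out 1 library moved the number of changed genes to between 1030 (without knockout 2) and 4521 (without control 3), and to 1422, 1192 and 1500 without knockout 1, knockout 3 and control 1.

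Other rises under the naming rule included DEFB4A, an inducible beta-defensin (4.45-fold), PI3, the elastase inhibitor elafin (4.75-fold), FN1, encoding fibronectin (3.45-fold), and TNC, the matrix protein tenascin-C (3.08-fold). FN1 and TNC were lowest in control 3, and without it their log2 values went from 1.79 to 1.59 and from 1.49 to 1.28. PDZK1IP1, FAM20C, a secreted-pathway kinase, and OASL, an interferon-induced gene, rose by 1.38, 1.26 and 1.23 on the log2 scale. DEFB4A has a near-identical copy and KRT6A, KRT6B and KRT6C resemble one another, so their reads may be shared. Falls included UBD, which encodes the ubiquitin-like modifier FAT10 (13.5-fold lower), BLMH, the protease bleomycin hydrolase (3.67-fold lower), ANXA10 (3.17-fold lower) and CALB2, the calcium-binding protein calretinin (3.25-fold lower). SRPX, FABP5, a fatty acid carrier of epidermis with many pseudogenes, NT5C3B, CCNC, the cyclin of the Mediator kinase module, and HMGN3 fell by 1.15, 1.14, 1.12, 1.07 and 1.03 on the log2 scale. Adjusted p for these 20 genes reached at most 0.000858 (limma, Benjamini-Hochberg). SRPX lies on chromosome X in the window of 20 to 40 Mb, where the median was -0.41 and 16 of 23 genes were lower.

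**Figure D2:**
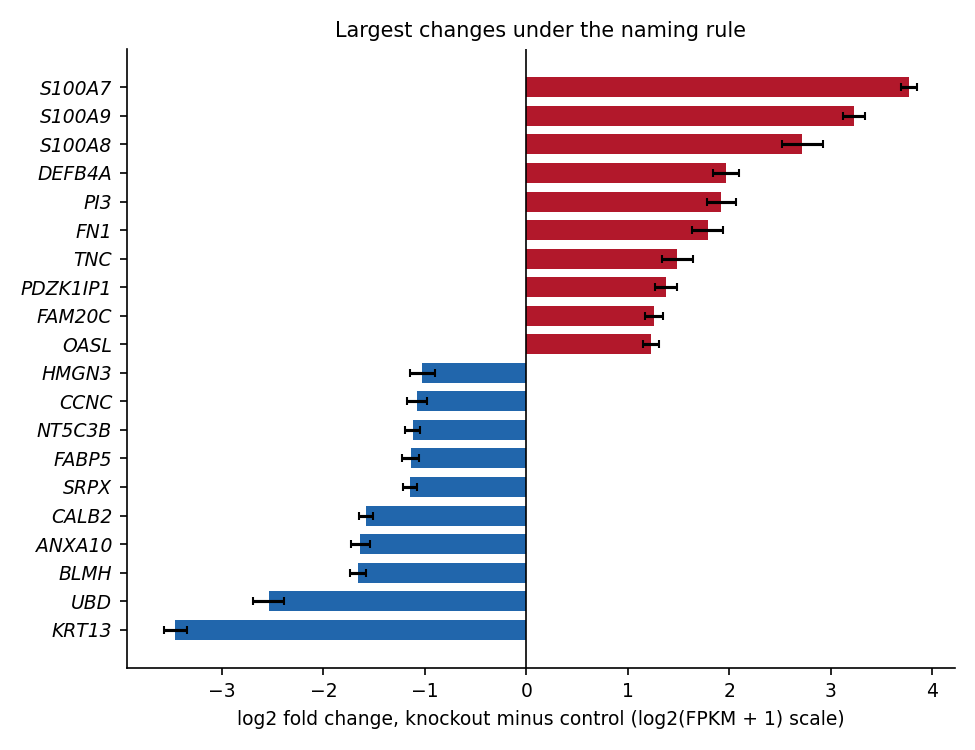
Log2 fold change, knockout minus control, of the 10 largest rises and 10 largest falls under the naming rule, with standard errors from limma. S100A7 stands at 3.77 and KRT13 at -3.46.

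EDAR itself was barely detected, at 0.226 ± 0.0217 FPKM in the knockout and 0.260 ± 0.0628 in the control, below the filter (limma without a filter, Benjamini-Hochberg adjusted p = 0.548). Its ligand EDA was also below the filter, at 0.173 ± 0.0288 against 0.351 ± 0.0444 FPKM, with a log2 fold change of -0.20 and adjusted p = 0.00849 without a filter. By the ratio of means EDA stood at 49.2% of control. It lies on chromosome X, where the window of 60 to 80 Mb had a median of -0.18 and 82.4% of genes below 0. EDARADD, the adaptor that binds the receptor's death domain, rose from 3.73 ± 0.471 to 5.20 ± 0.103 FPKM (log2 fold change 0.40, limma with Benjamini-Hochberg adjusted p = 0.0125), a call lost without knockout 2 (adjusted p = 0.0672). TAB2 and MAP3K7 (TAK1), which link TRAF proteins to the IKK kinases, fell to 62.8% and 65.2% of control. Both lie on a stretch of chromosome 6 where most genes were lower, at its 31.2 and 46.3 percentiles. TAB1 had a log2 value of 0.25 and did not pass (adjusted p = 0.0642). It passed with the replicate block (0.0448), with array weights (0.00611) and without control 2 (0.0474), but after a per-library correction for GC content and transcript length its value was 0.11 (adjusted p = 0.197, and 0.188 with the block). Of 8 tested members of EDA/EDAR signalling, 1 rose, 2 fell and 5 did not pass; adjusted over the list alone, 2 rose and 3 fell. The GC and length correction left 1 higher and 3 lower (1 and 2 with the block). As a list it did not pass camera (adjusted p = 0.818).

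NF-kB genes moved in both directions. Of 18 subunits and regulators, NFKBIZ and BCL3, which encode nuclear IkB proteins, rose to 139% and 137% of control, NFKBIE, encoding a cytoplasmic inhibitor, fell to 62.6%, and 15 did not pass. CHUK, encoding IKK-alpha, was at 83.6% of control and did not pass (adjusted p = 0.0509). It passed with the replicate block (0.0395), with array weights (3.36e-05) and without control 3 (0.00341), but after the GC and length correction its log2 value went from -0.25 to -0.07 (adjusted p = 0.367, and 0.272 with the block). Adjusted over the list alone the counts were again 2 higher and 1 lower, and camera gave adjusted p = 0.818, direction up. After the GC and length correction the counts were 2 higher and 6 lower, with TNIP2, MAP3K14, RELB, NFKBIB and NFKB2 past the threshold on the lower side, and the camera direction turned to down (adjusted p = 0.441). With the replicate block added they were 1 higher and 5 lower, BCL3 (adjusted p = 0.0532) and NFKB2 (0.0793) not passing. NF-kB target genes numbered 24, of which LCN2, PTGS2 and TNFAIP2 rose, PLAU, BIRC3 and SOD2 fell, and 18 did not pass; adjusted over the list alone, 3 rose and 4 fell (camera adjusted p = 0.889). Corrected for GC and length, 5 were higher and 4 lower (5 and 3 with the block). SOD2 lies on the chromosome 6 stretch where most genes were lower, at its 89.6 percentile, so it fell less than most genes there. LCN2, an iron-sequestering antimicrobial protein, went from 1171 ± 126 to 2095 ± 43.7 FPKM. Chemokine CXCL8 measured 225.5 ± 16.8 against 226.3 ± 17.6 FPKM (log2 fold change -0.01, adjusted p = 0.971), but after the GC and length correction its log2 fold change was 0.36 (adjusted p = 0.0047, and 0.00971 with the replicate block added). Among 5 tested EDAR targets of skin appendages, WNT10A rose (log2 fold change 0.42, limma with Benjamini-Hochberg adjusted p = 0.00872) and 4 did not pass, with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.818). FST and BMP2 had log2 values of -0.11 and -0.11, and CCN2 had -0.34 (adjusted p = 0.0655). CCN2 passed with the replicate block (0.0265), as TPM (0.0297), with array weights (0.00546) and without control 2 (0.0178), but not after the GC and length correction (0.067, and 0.0508 with the block). Without knockout 2 the calls of NFKBIE (adjusted p = 0.0986), BCL3 (0.0585) and WNT10A (0.0518) were lost, and without knockout 1 that of NFKBIE (0.0744), and without knockout 3 that of BCL3 (0.0547). NFKBIE also lost its call without a filter (0.0555), and its log2 value went from -0.51 to -0.26 with array weights, as that of BIRC3 went from -0.53 to -0.33 after the GC and length correction.

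Keratinocyte state genes split by group. Of 15 wound keratins and alarmins with deposited values, 11 were tested. Of these 8 rose and 3 did not pass, with 9 higher adjusted over the list alone. Besides the S100 genes, those that rose included KRT6A and KRT6B, keratins of activated epidermis whose reads may be shared (1.89-fold and 4.72-fold). SLPI, a protease inhibitor, also rose (2.14-fold). Camera gave adjusted p = 7.04e-11 with the preset correlation and adjusted p = 0.274 with an estimated correlation. Of 39 differentiation genes in the file, 10 were tested, of which 6 fell and 4 did not pass, with 6 lower and 1 higher adjusted over the list alone. KLK5, a protease that sheds corneocytes, fell to 48.3% of control, SPRR1A and SPRR2A, cornified envelope precursors, to 30.3% and 35.6%, and OVOL1, a transcription factor of differentiating epidermis, to 69.2%. For that list camera gave adjusted p = 0.00665, and adjusted p = 0.306 with an estimated correlation; without a filter on low values the call was lost (adjusted p = 0.149). All 3 of the SPRR and OVOL1 genes were near the filter, at under 4 FPKM, and OVOL1 lost its call without knockout 1 (adjusted p = 0.0566) or knockout 3 (0.0575). A pseudocount of 0.1 moved the log2 values of KRT6B from 1.33 to 2.12, SPRR1A from -1.16 to -1.86, SPRR2A from -0.80 to -1.36 and OVOL1 from -0.31 to -0.50.

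Basal and hemidesmosome genes were tested for 15 members. KRT5, the basal keratin, rose from 145.4 ± 8.33 to 257.0 ± 8.83 FPKM, COL17A1, a hemidesmosome collagen, rose 1.63-fold, and LAMA3 and LAMB3, chains of laminin-332, rose 1.38-fold and 1.29-fold. The other 11 did not pass, and adjusted over the list alone 6 rose and 1 fell. After the GC and length correction 5 were higher and 3 lower, with or without the block, the lower ones being KRT15, BCAM and ITGA3. KRT15 and ITGA3 lie on a stretch of chromosome 17 where most genes were lower. Before the correction they stood at its 70.2 and 83.4 percentiles, so they fell less than most genes there. COL17A1 and LAMA3 were lowest in control 3. As a list it missed the threshold (camera adjusted p = 0.0627). It passed without control 1 (0.0325), control 2 (0.0166) or knockout 3 (0.0461), as TPM (0.0462) and without the chromosome 6 and 17 regions (0.0153). It did not pass under any other alternative, among them without control 3 (0.248), with array weights (0.224), after the GC and length correction (0.231, and 0.276 with the replicate block) and with an estimated correlation (0.669). LAMA3 and LAMB3 each lost their call without any 1 of the knockout libraries or without control 1 (adjusted p between 0.0503 and 0.148), and LAMA3 also without a filter (0.0891) and as TPM (0.0546). Without control 3 the log2 value of LAMA3 went from 0.47 to 0.29, and after the GC and length correction that of LAMB3 went from 0.37 to 0.20. Of 6 simple and mucosal keratins, KRT13, KRT8 and KRT18 fell and 3 did not pass, also adjusted over the list alone (camera adjusted p = 0.0724). That list passed after the GC and length correction (0.014, and 0.0177 with the replicate block), without control 1 (0.0325) and as TPM (0.0462), and under no other alternative; without the chromosome 6 and 17 regions, which hold KRT13, it stood at 0.274. KRT8 and KRT18 pair in simple epithelia and stood at 70.9% and 79.2% of control; KRT18 lost its call without any 1 of the knockout libraries (adjusted p between 0.0904 and 0.115). Cell-cell junction genes (27 tested) had 4 higher, 3 lower and 20 not passed, the same counts adjusted over the list alone (camera adjusted p = 0.469). Once corrected for GC and length, 5 were higher and 7 lower (7 and 7 with the block). CLDN1, a tight junction claudin, fell to 63.4% of control and PERP, a desmosome protein, to 70.6%, while TJP1 and PKP3 rose 1.47-fold and 1.33-fold. TJP1, at 0.52 on the log2 scale, lies on chromosome 15 in the window of 20 to 40 Mb. The median there was 0.34, and 23 of 36 genes were higher by limma. PERP and PKP3 lost their calls without knockout 2 (adjusted p = 0.0651 and 0.0593), and PKP3 went from 0.41 to 0.24 on the log2 scale after the GC and length correction.

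Of 22 tested members of the cytosolic heat shock list, 11 fell and 11 did not pass, and adjusted over the list alone 12 fell and 1 rose. HSP90AA1, the inducible HSP90, went from 1006 ± 37.1 to 695.2 ± 38.4 FPKM, and CHORDC1, DNAJB4 and BAG2, cochaperones of HSP90 or HSP70, stood at 66.5%, 62.2% and 72.9% of control, with DNAJB4 going from -0.61 to -0.31 on the log2 scale after the GC and length correction. HSPA1A and HSPA1B, near-identical copies of inducible HSP70, fell to 0.768 and 0.794 of control, although their reads may be shared. Camera gave adjusted p = 0.000557, and adjusted p = 0.274 with an estimated correlation. Of 22 genes of the unfolded protein and integrated stress response, 7 rose and 15 did not pass, with 8 higher adjusted over the list alone and 11 higher after the GC and length correction (9 higher and 1 lower with the block; camera adjusted p = 0.00333, and adjusted p = 0.555 with an estimated correlation). The risers with the smallest p, PHGDH and ASNS, which make serine and asparagine, SESN2 and CHAC1, are targets of ATF4 in amino acid stress. HSPA5, the chaperone BiP, had a log2 value of 0.09 (adjusted p = 0.424).

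More interferon-stimulated and TGF-beta response genes rose than fell, but most did not pass. Of 23 interferon-stimulated genes, 9 rose, 2 fell and 12 did not pass, with 11 higher and 3 lower adjusted over the list alone. OAS2, OASL, IFI44 and DDX60, antiviral genes, rose 3.26-fold, 2.72-fold, 2.15-fold and 2.16-fold, while IFIT2 and IFIT5 fell to 0.682 and 0.734 of control (camera adjusted p = 0.00268, and adjusted p = 0.274 with an estimated correlation). Of 17 TGF-beta response genes, 5 rose, 1 fell and 11 did not pass, with 8 higher and 2 lower adjusted over the list alone. PMEPA1, TGFBI and CCN1, matrix and feedback genes of that pathway, rose 1.93-fold, 1.78-fold and 1.54-fold, and the receptor gene TGFBR1 fell (camera adjusted p = 0.00333, and adjusted p = 0.274 with an estimated correlation). Of 11 epithelial-mesenchymal transition genes, FN1, TNC, SNAI2, AXL and LOXL2 rose, MMP1 and MMP10 fell and 4 did not pass, the same counts adjusted over the list alone. MMP1 went from -0.75 to -1.40 on the log2 scale with a pseudocount of 0.1. Camera gave adjusted p = 0.0416 for these 11 genes, and adjusted p = 0.279 with an estimated correlation. That list lost its call without control 2, knockout 2 or knockout 3 (adjusted p = 0.0508, 0.05002 and 0.0508), and also without a filter (0.39), with a pseudocount of 0.1 (0.0654), with median-of-ratios scaling (0.0515) and without the chromosome 6 and 17 regions (0.0562).

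Of 20 EGFR ligand and feedback genes, 9 fell, 1 rose and 10 did not pass, with 9 lower and 2 higher adjusted over the list alone, and 9 lower and 3 higher after the GC and length correction (7 and 2 with the block). AREG and EREG, ligands of the receptor, stood at 60.3% and 48.4% of control and DUSP5, a phosphatase of ERK, at 54.4%, whereas the early response factor EGR1 rose 1.62-fold. Camera gave adjusted p = 0.0284, and adjusted p = 0.274 with an estimated correlation; the call was lost without control 2 (0.0508) and with a filter at 5 FPKM (0.206).

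Several lists served as checks or did not pass camera. Among STUB1 neighbours on chromosome 16, 5 of 15 rose, JMJD8 fell and 9 did not pass, with 6 higher and 1 lower adjusted over the list alone, and 2 higher and 2 lower after the GC and length correction (3 and 2 with the block; camera adjusted p = 0.0248; adjusted p = 0.665 with an estimated correlation; 0.896 after the GC and length correction; 0.173 with a filter at 5 FPKM). That call was also lost without knockout 2, control 1 or control 2 (adjusted p = 0.099, 0.108 and 0.0508). Histone genes, whose mRNAs largely lack poly(A) tails, had 4 of 6 higher and 2 not passed, 5 higher adjusted over the list alone (camera adjusted p = 0.00474; adjusted p = 0.357 with an estimated correlation; 0.131 without a filter). H2BC5 rose 1.77-fold. Mitochondrially encoded mRNAs had 0 of 13 past the limma threshold and 0 adjusted over the list alone, with 3 at an unadjusted p under 0.05, and as a list they stood above other genes (camera adjusted p = 0.00474; adjusted p = 0.61 with an estimated correlation; 0.0528 with array weights). Of the 13, 3 passed after the GC and length correction, all higher (2 with the block). MT-CO1, MT-CYB and MT-ND4 (adjusted p = 0.0801, 0.0508 and 0.0509) passed after that correction (0.0298, 0.0314 and 0.0313), without the variance trend (0.0206, 0.0231 and 0.0243), with array weights (0.00241, 0.00082 and 0.000724) and without control 3 (0.00261, 0.00264 and 0.00316). MT-CYB also passed with a pseudocount of 0.1 (0.0495) and MT-ND4 as TPM (0.0377), and MT-ND4L passed with array weights (0.0193) and without control 3 (0.0243). The log2 value of MT-ND4L went from 0.52 to 0.23 with array weights and to 0.22 without control 3. Counts of higher and lower genes were 7 and 3 of 20 for cholesterol synthesis (8 and 3 adjusted over the list alone), 2 and 5 of 21 for hypoxia, 2 and 4 of 15 for p53 targets, 3 and 2 of 28 for proliferation and 0 and 4 of 20 for NRF2 targets (each the same adjusted over the list alone), and 1 and 2 of 10 for Wnt targets (2 and 2 adjusted over the list alone). After the GC and length correction the counts were 9 and 2 for cholesterol synthesis, 2 and 4 for hypoxia, 3 and 5 for p53 targets, 7 and 2 for proliferation, 1 and 6 for NRF2 targets and 2 and 2 for Wnt targets. With the block they were 8 and 2, 1 and 5, 3 and 5, 6 and 2, 2 and 6, and 2 and 2. None of these 6 lists passed camera (adjusted p between 0.102 and 0.818), and cholesterol synthesis passed after the GC and length correction (0.0285). The NRF2 genes that fell were ME1, GCLC, FTH1 and GCLM, of antioxidant metabolism. Fibroblast, melanocyte and leukocyte markers had 0, 2 and 1 tested members, the highest being COL1A1 at 0.48, PMEL at 5.34 and CD68 at 22.6 FPKM. By fry 10 lists passed, not all of them those of camera. The stress response, STUB1 neighbour and mitochondrial lists did not pass fry (adjusted p = 0.0569, 0.266 and 0.212), whereas simple and mucosal keratins and NRF2 targets did (0.00704 and 0.0304). With an estimated correlation 0 of 24 lists passed camera.

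**Figure D3:**
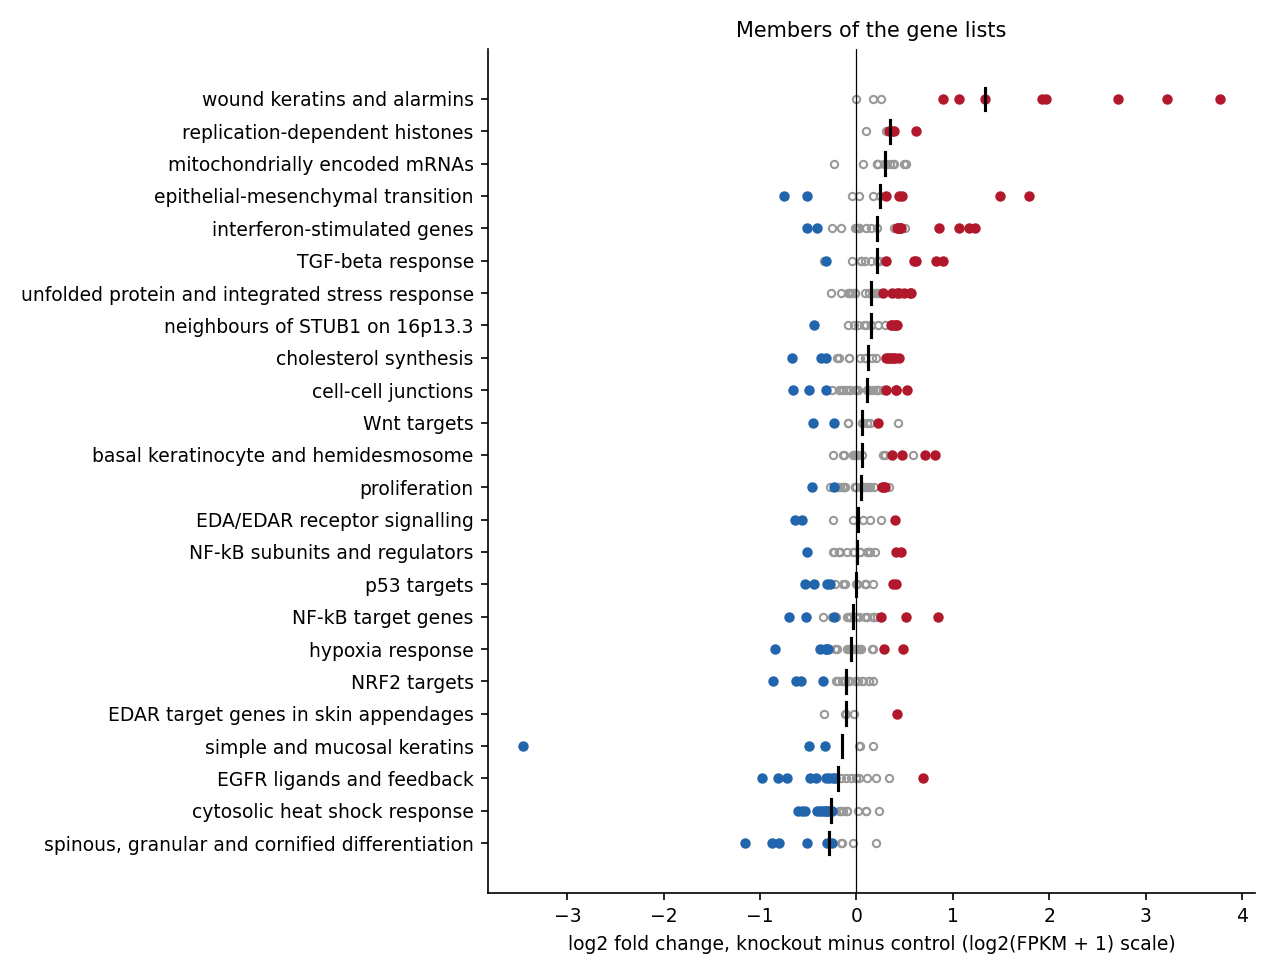
Log2 fold change, knockout minus control, of each tested member of the 24 lists, filled where the gene passed the adjusted threshold (red higher, blue lower) and open where it did not, with the list median as a black bar. Wound keratins and alarmins have a median of 1.33 and differentiation genes one of -0.28.

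Genes along 2 chromosome segments were lower together, a pattern sought after the data were seen. On chromosome 6, from SMAP1 at 70667776 to the last tested gene, 198 of 231 genes fell and 0 rose by limma, 98.3% lay below 0 and the median log2 fold change was -0.53. Among those at 10 FPKM or more, the median knockout level was 63.9% of control. On chromosome 17, from 40627356 on, 225 of 349 genes fell and 3 rose, 94.0% lay below 0, and the median was -0.35, with 74.0% of control among genes at 10 FPKM or more. The rest of chromosome 17 had a median of -0.12, so its edge was less sharp. Chromosome 15 had a median of 0.34 over its first 30 tested genes, up to MEIS2. Shifts were not limited to these segments. Among 20 Mb windows, medians beyond those of nearly all 1000 shuffles of gene order (p of at most 0.002) also stood on chromosome 8 at 120 to 140 Mb (-0.34, 21 of 35 genes lower) and on chromosome X at 20 to 40 (-0.41, 16 of 23 lower), 100 to 120 (-0.28, 28 of 60 lower) and 120 to 140 Mb (-0.27, 19 of 37 lower). On the higher side was chromosome 5 at 0 to 20 Mb (0.29, 15 of 34 higher). After the GC and length correction these medians were -0.25 on chromosome 8, -0.35, -0.15 and -0.15 on chromosome X, and 0.25 on chromosome 5. Every chromosome X window had a median below 0 before that correction. The medians in the 3 knockout libraries, against the control mean, were -0.48, -0.62 and -0.53 on chromosome 6 and -0.35, -0.34 and -0.36 on chromosome 17. These regions held 5.15% of tested genes and 28.2% of lower calls (423 genes), among them TAB2, MAP3K7, PERP, CCNC and HMGN3 on chromosome 6 and KRT13, KRT10 and NT5C3B on chromosome 17. KRT13 stood at -3.11 on the log2 scale relative to its region's median, whereas TNFAIP3 on chromosome 6 and KRT19 on chromosome 17 had values of 0.11 and 0.04. SOD2, CCN2 and ME1 lie on the chromosome 6 region at its 89.6, 80.5 and 6.93 percentiles, and MAP3K14 on that of chromosome 17 at its 71.9 percentile. Without the regions, 1982 genes changed, 993 higher and 989 lower.

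**Figure D4:**
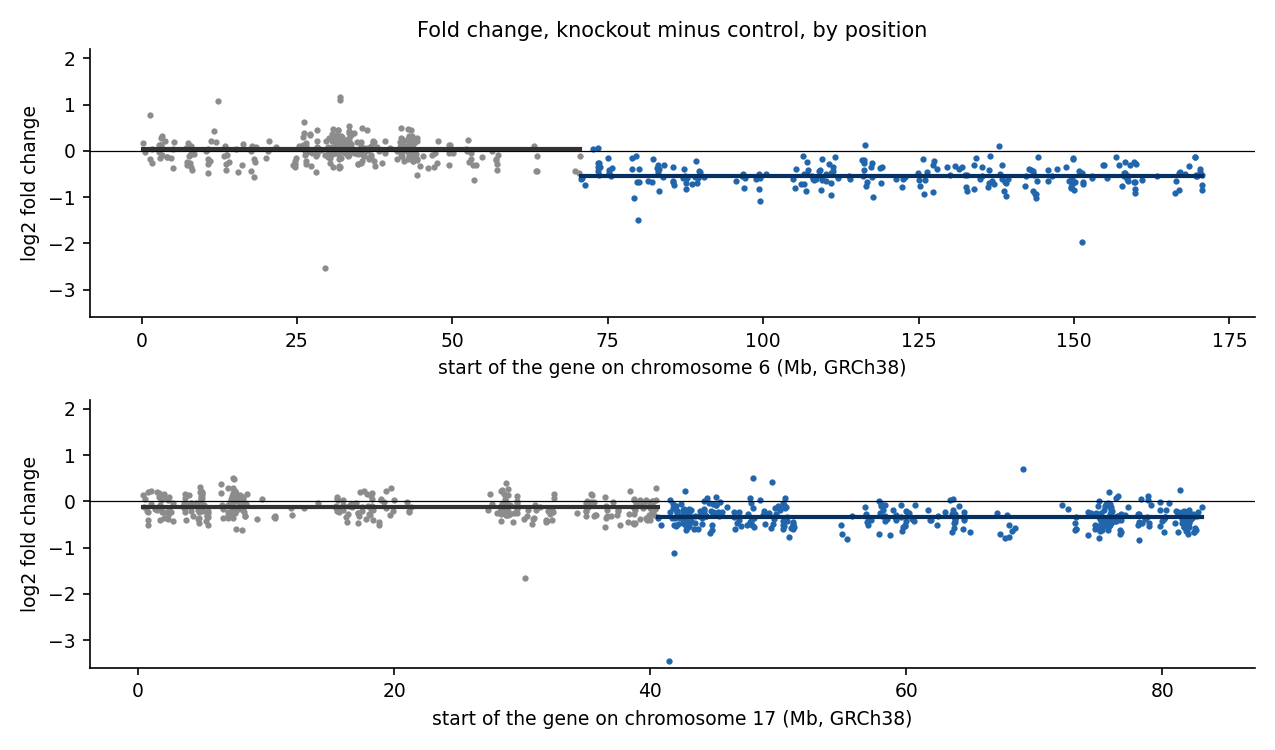
Log2 fold change of each tested gene against its start on chromosomes 6 and 17 (Mb, GRCh38), with genes of the 2 regions in blue and others in grey, and bars at the median of each part. The median on chromosome 6 is 0.04 before SMAP1 and -0.53 from there on.

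Fold changes also followed GC content. Across genes, which are not independent replicates, the rank correlation of log2 fold change with transcript GC content was 0.461, and the median GC content was 57.0% for genes that rose and 42.6% for genes that fell. S100A7, KRT13, UBD and FN1 stayed past the threshold after a per-library correction for GC content and length (limma, Benjamini-Hochberg), with log2 fold changes of 3.75, -3.49, -2.34 and 1.81.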

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

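The corrections for GC content and transcript length and the fits without the genes of the chromosome 6 and 17 regions were chosen after the data were seen. STUB1 kept its direction and stayed past the threshold under all 17 alternatives run. The number of genes changed at least 2-fold moved from 41 to 90 with a pseudocount of 0.1, to 26 with a filter at 5 FPKM, since fewer genes were tested, and to 71 as TPM, where the cause was not tested. It ran from 40 to 54 when 1 library was left out. The number of changed genes moved from 2579 to 6437 with array weights, and the cause was not tested. Leaving out 1 library gave between 1030 (without knockout 2) and 4521 (without control 3), with 1422, 1192 and 1500 without knockout 1, knockout 3 and control 1. Passing lists numbered 7 with a filter at 5 FPKM and 0 with an estimated correlation, against 11, and 9 to 12 when 1 library was left out. With the replicate block 3051 genes changed, 42 of them at least 2-fold, and 11 lists passed; among named genes it brought TAB1, CCN2 and CHUK past the threshold and changed no other call. After the GC and length correction 3376 genes changed, 40 at least 2-fold, and 12 lists passed. With the block added these were 3137, 40 and 12. Of the 2568 calls that could be compared, 1988 stayed with the same sign after the correction (1907 with the block) and 6 turned direction. FST, which had not passed, went from -0.11 to 0.00740612 on the log2 scale under both corrected fits; the cause was not tested. Without the region genes 1982 genes changed, 34 at least 2-fold. Over the other comparisons of named genes with their alternatives, 1336 kept side and direction, 52 lost a call and 28 gained one; for lists other than EDA/EDAR signalling and the NF-kB lists these were 323, 29 and 11, and 13 turned direction without passing. Direction turned, never past the threshold, in 8 lists (camera adjusted p in brackets). For EDA/EDAR signalling it turned without the regions (0.380739), and for NF-kB subunits after the GC and length correction (0.441142, and 0.43979 with the block). For NF-kB targets it turned without a filter (0.508283), with the block (0.978383) and without knockout 3, control 1 or control 2 (0.708118 to 0.94025 over all left-out libraries). EDAR targets turned with a filter at 5 FPKM (0.82606), without the regions (0.972538) and without knockout 1 or control 3 (range 0.708118 to 0.991619). Wnt targets turned with a filter at 5 FPKM (0.871843), with array weights (0.952511), after the GC and length correction (0.853067, and 0.874481 with the block) and without control 3 (range 0.621095 to 0.991619). Array weights turned p53 targets and hypoxia (0.952511 each), and leaving out control 3 turned p53 targets (range 0.403254 to 0.991619) and cell-cell junctions (0.178716 to 0.991619). Why was not tested. Depth could not be read directly from FPKM, so the counting error of low genes such as EDAR and EDA is unknown.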

Other observations

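All tests of explanations below were written down only after the results they measure had been seen, the splits of the libraries included.

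Further genes outside the naming rule changed at least 2-fold, and those given here were chosen after their values were seen. AKAP12, a scaffold of protein kinase A, was listed at 0 in all 3 knockout libraries and at 2.95 ± 0.498 FPKM in the control. CDA, the cytidine deaminase of pyrimidine salvage, measured 0.026 ± 0.045 against 2.53 ± 0.763 FPKM. ELOVL4, which elongates very long fatty acids of the epidermal barrier, fell 7.62-fold, and DBN1, the actin-binding protein drebrin, fell 4.34-fold. AKAP12 and ELOVL4 lie on the chromosome 6 region with lower expression. Among rises, COL16A1, a collagen, went up 2.98-fold, CFB, complement factor B, 2.45-fold, EDN1, endothelin-1, 2.45-fold, ACKR3, a chemokine scavenging receptor, 2.27-fold, and TNIP3, an inhibitor of NF-kB signalling, 2.99-fold. Limma gave Benjamini-Hochberg adjusted p of at most 0.000122952 for these genes.

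As a source of the lower expression along chromosomes 6 and 17, a GC or length bias would have brought the medians near 0 once the trend was removed. They stayed at -0.436343 on chromosome 6 and -0.400477 on chromosome 17. The edges of both regions were placed on fold changes after that correction, so low medians were built in. The region medians could therefore not exclude the bias. Edges of the 20 Mb windows were not fitted. After the correction, windows of chromosome 6 from 80 to 180 Mb had medians of -0.40 to -0.48, and that of 60 to 80 Mb, which holds the edge, -0.27. Windows of chromosome 17 from 40 Mb on went from -0.31, -0.38 and -0.38 to -0.32, -0.43 and -0.52. These values argue against the removed GC and length trend as the sole source on either chromosome. Fewer DNA copies in the knockout cells could neither be supported nor excluded: an earlier test on the share of genes below 0 (98.3% and 94.0%) was dropped because the regions were found from the same fold changes. Its replacement, the interquartile range, was 0.986889 and 0.994108 times that of genes elsewhere, values known when it was put in, and it lends no support either. TAB2 and MAP3K7 may have fallen with their region, since they lay at its 31.1688 and 46.3 percentiles. No DNA was measured here, and the labels name no second clone, so loss of STUB1 itself stays open beside a difference between clones.

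The trend of fold changes with GC content was weighed next. Control 3 as the sole source is argued against, since without it the rank correlation across genes was 0.507932. Without knockout 2 that correlation was 0.342, against 0.461 with all libraries. Knockout 2 had the steepest GC slope relative to the mean of all libraries, 0.144 log2 units per 10% GC. Knockouts 1 and 3 had 0.0251 and 0.0467. The lowest knockout GC slope exceeded the highest control slope by 0.0520045 log2 units per 10% GC, while slopes within the knockout ranged over 0.119. A library-to-library GC bias unrelated to genotype could therefore not be told apart from an effect of genotype with 3 libraries in each group.

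The rise of S100A7, S100A8, S100A9, DEFB4A and PI3 was weighed against leukocytes in the cultures. That of the S100A genes was also weighed against extra copies of their chromosome 1 segment. DEFB4A and PI3 lie on chromosomes 8 and 20. Of the 12 leukocyte markers fixed beforehand, 11 stayed under 1 FPKM in both groups, the highest at 0.143 FPKM in the knockout, while CD68 stood at 23.7 against 21.5 FPKM, 1.1014-fold, where S100A9 rose 9.5-fold. This test over the whole list replaced an earlier one on 4 of its markers, and all values were known by then. The 72 other tested genes within 2 Mb of the S100A genes had a median log2 fold change of 0.0694387, against 2.72 to 3.77 for the S100A genes. Leukocytes are thus argued against, and so are extra copies, the latter for the S100A genes alone. An effect of STUB1 loss or of a clonal difference may remain, as a hypothesis that these libraries cannot separate.

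Of the 10 splits of the 6 libraries into 3 and 3, 1 split, the real one, gave as many as 2579 changed genes and 1 split as many as 41 changed at least 2-fold. The highest of the other splits gave 0 in both cases by limma, and 707 genes at an unadjusted p under 0.05 against 4287. The 3 other splits that part every numbered pair gave 0 genes each, with 197, 41 and 23 at an unadjusted p under 0.05. With 10 splits the share cannot go under 0.05. Every other split also mixes knockout and control libraries, so the difference between them adds to the spread within groups and lowers the calls. The counts of the other splits therefore lend no support to the real one.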
